A study of Takifugu alboplumbeus with 24 samples.

How the data were processed

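The values are the authors' deposited FPKM, given with 2 decimals for 24 libraries and 24935 genes and transcripts. By the deposited table these are 24006 genes, 699 additional transcripts and 230 noncoding transcripts, and gene names follow RefSeq models of the related pufferfish Takifugu rubripes; 14275 genes carry only an LOC symbol, of which 7989 were tested. Per the submitters' notes, poly-A RNA was made into strand-specific libraries, read as pairs of 100 bases, aligned with HISAT2 2.0.4 and counted with RSEM 1.2.12. The genome build is not given in the sources used here, and sequencing depth is unknown, so no interval from read counting and no detection floor is given. Sample groups, by moon phase and month, are taken from the labels. The tide was assigned from the moon phase, and the lunar cycle from the order of the sampling dates. The labels do not say how many fish a library holds. The tide and the moon phase varied between dates only, so the 8 dates are the units for them, and the 3 libraries of a date are not independent. The p-values of single genes combine the spread between dates and between libraries of a date. The test among the 8 dates uses only the spread within dates. The p-values of lists from camera rest on the spread between genes. Every library was used and no library was removed.

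FPKM was changed to log2(FPKM + 1), which understates fold changes of genes with low values, and genes with a mean FPKM of at least 1 over all fish were tested (17058). Correlations between libraries lay between 0.934 and 0.983, with a median of 0.974 within a date and 0.965 between dates, and no pair of libraries was identical. The first principal component held 26.4% of the variance and the next 9.69%. Comparisons used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, with an intensity trend, the 4 moon phases as groups and the sampling date as a random block, and Benjamini-Hochberg adjustment over genes at a threshold of 0.05. The within-date correlation was 0.264 for the tide, 0.276 for the trend and 0.290 for the interaction. The trend model held the tide and the week number, the interaction model the tide and the lunar cycle, and the test among dates the 8 dates without a block. The tests, the lists and most alternative settings were fixed before the data were examined. The covariates that hold the library FPKM sum or the pituitary score without gonadotropin genes, the model with 2 tide groups, and the fits of the exact tests and pituitary scores without Waxing moon May fish 2, were added after the data had been seen.

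The 21 gene lists and 16 cell type lists were tested with camera at a preset correlation of 0.01, with the correlation estimated from the residuals, and with fry, and adjusted over the lists of each kind. The gene lists were the reproductive axis, pituitary cells, the circadian clock, opsins with light and melatonin, immediate early genes, the C/EBP family, the glucocorticoid and stress axis, heat shock, the thyroid axis, the prostaglandin pathway, hypothalamic neuropeptides, neurotransmitter enzymes, the interferon response, inflammation, the cell cycle, cholesterol biosynthesis, oxidative phosphorylation, cytosolic ribosomal proteins, hypoxia, steroid synthesis and the unfolded protein response. Members were matched by symbol with paralogue suffixes, and genes with only an LOC symbol by an unambiguous product name. Ribosomal protein kinases and the like (rps6k, rps19bp, rpl7l1, rpl22l1) were kept out of the ribosomal list. Lists overlap: 10 of 21 tested pituitary genes and 4 of 21 reproductive genes are also in another list. Reads shared between paralogues make the levels of close copies uncertain. Annotation terms in the deposited table that held 10 to 300 tested genes were tested with camera at the preset correlation only.

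For the tide, the genes named are the 12 largest increases and the 12 largest decreases among genes that passed, had the same sign in both lunar cycles and had a symbol or a product name other than uncharacterized. Other comparisons name 5 genes per direction and the trend 10 per direction, and where fewer than 5 passed these are the smallest p-values, said not to pass. The test among dates names the 10 smallest p-values. Each list described gives up to 4 members with the smallest p, and gnrh1, cebpd, lhb, fshb, cga, gh1, prl, pomc and tshb are always given. The 5 genes gnrh1, cebpd, lhb, fshb and cga were also tested by exact two-sided permutation of 4 spring and 4 neap date means.

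As a check of the tests, log2 values were simulated with the mean and spread of each gene. Changes of known size were put into 200 simulated genes per comparison. The simulated genes varied independently of each other, unlike the real ones, so the shares recovered hold under that model only. For the tide, 80.6% of changes of log2 0.5, 97.0% of those of 1 and 100% of those of 2 were recovered, and for new against full moon 49.3%, 91.0% and 93.9%. For waxing against waning moon the shares were 52.2%, 95.5% and 98.5%, for the trend, as a change over the whole series, 43.3%, 79.1% and 95.5%, and for the interaction 19.4%, 79.1% and 95.5%. Genes into which no change had been put for the comparison were also called: 16 for the tide, 22 for waxing against waning moon and 11 for each other comparison. How many of these carried a change put in for another comparison was not counted. Random splits of the dates used seed 1 and at most 100 draws. The splits and the fits with fish or dates left out took the within-date correlation from every 8th gene to save time.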

Results

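The data are gene expression levels in the brain of wild male grass puffers (Takifugu alboplumbeus), a fish that spawns on beaches around the spring tides. The fish came from a spawning site at Minamichita in Japan, and the tissue was 1 piece holding the ventral telencephalon, the hypothalamus and the pituitary, taken at about 19:00 after the live fish had been brought to the laboratory. Sampling was weekly at 8 dates from May to July, with 3 libraries per date and 24 libraries in all. The new and full moons are the spring tides (4 dates, 12 libraries) and the waxing and waning moons the neap tides (4 dates, 12 libraries). The labels do not say that each library is 1 animal; each is called 1 fish here. Values are FPKM for 24935 genes and transcripts, of which 17058 had a mean of at least 1 and were tested. Read depth is unknown, because FPKM values keep no read numbers, so no counting interval is given.

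The libraries of the spring tides held higher levels of pituitary hormone transcripts than those of the neap tides. These levels alone do not tell a larger share of pituitary from a higher expression of hormone genes. A pituitary score, the mean log2 level of 8 pituitary hormone genes, was 10.7 ± 0.35 at spring tide and 9.14 ± 0.44 at neap tide (SD, n = 4 dates, exact permutation p = 0.0286, two-sided, the smallest p that 70 assignments of 8 dates allow). Without the 3 gonadotropin genes the score was 10.2 ± 0.34 against 9.03 ± 0.85 (exact permutation p = 0.0286, n = 4). Without Waxing moon May fish 2 the difference of the full score went from 1.60 to 1.1 (exact permutation p = 0.0571, n = 4) and that of the score without gonadotropins from 1.14 to 0.67 (exact permutation p = 0.0286, n = 4). The sum of FPKM over all genes was 508 ± 24.8 kFPKM at spring tide and 463 ± 26.1 kFPKM at neap tide (exact permutation p = 0.0857, n = 4). Waxing moon May, a neap date, had a sum of 501 ± 19.8 kFPKM (SD, n = 3 fish), within the range of the spring dates. In fish 2 of that date all 8 hormone genes were low: pomc was 300 FPKM against a median of 12898 in the other libraries, gh1 was 18.1 against 883 and cga was 80.7 against 7019.

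**Figure D1:**
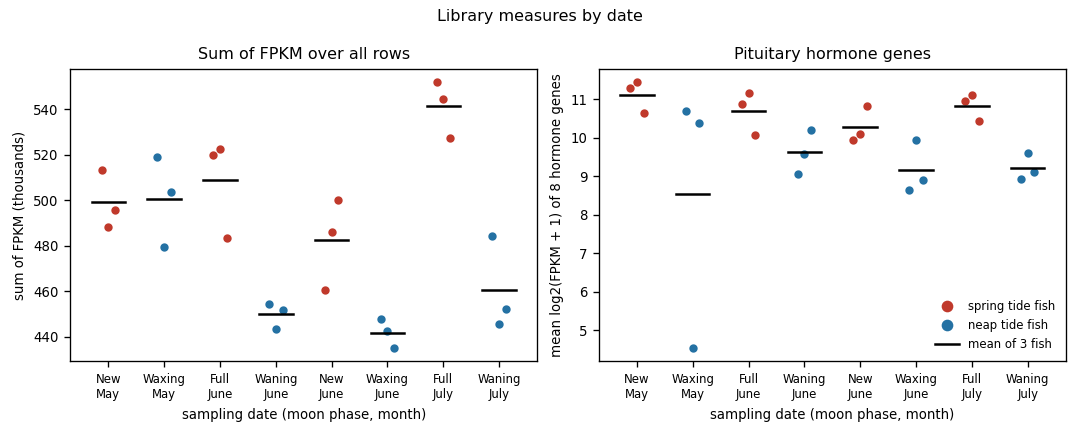
Sum of FPKM in kFPKM (left) and mean log2(FPKM + 1) of 8 pituitary hormone genes (right) for each fish, by sampling date; points are fish, red at spring and blue at neap tide, and bars are means of 3 fish. The hormone score was 10.7 at spring and 9.14 at neap tide, and 1 fish of Waxing moon May lay at 4.54.

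The main question of the design is which genes differ between spring and neap tide. Of the gonadotropin genes of the pituitary, lhb rose at spring tide, cga came close to the threshold and fshb did not pass. The beta subunit of luteinizing hormone, lhb (LOC101078229), rose from 1716 ± 1561 FPKM at neap to 6337 ± 1797 FPKM at spring tide (SD, n = 4 dates), a log2 change of 3.20 with an SE of 0.93 (limma, adjusted p = 0.0461), and lay on the side of its tide in 21 of 24 fish. The shared alpha subunit cga was 14354 ± 6154 against 3616 ± 918 FPKM, a log2 change of 2.30 with an SE of 0.69, which just missed the threshold (limma, adjusted p = 0.0505, 22 of 24 fish). The transcription factor cebpd rose from 22.2 ± 5.37 to 45.2 ± 17.7 FPKM (log2 change 0.97, SE 0.25, limma, adjusted p = 0.0331, 20 of 24 fish). The gonadotropin-releasing hormone gene gnrh1 had 21.9 ± 6.10 FPKM at spring and 7.51 ± 7.91 at neap tide, a log2 change of 1.60 with an SE of 0.62 that did not pass (limma, adjusted p = 0.107); its level at Waxing moon May, 19.2, lay close to those of the spring dates. The study is known to discuss gnrh1, cebpd and prostaglandin E2, so these 2 genes and the prostaglandin genes are not independent evidence.

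Exact two-sided permutation tests of the 8 date means, set beside limma for the 5 targeted genes, gave p = 0.0286 for lhb, cga and cebpd, the smallest value possible (adjusted over the 5 genes, p = 0.0476 for each). The exact p was 0.114 for gnrh1 (adjusted 0.143) and 0.343 for the follicle-stimulating hormone subunit fshb. Without Waxing moon May fish 2, the library low in hormone transcripts, the exact p was 0.0571 for lhb and cebpd and 0.0286 for cga, and 0 of the 5 genes passed after adjustment (adjusted p = 0.0952 for each of these 3). In limma lhb (log2 change 2.75, adjusted p = 0.0404) and cebpd (0.95, adjusted p = 0.0403) passed without that fish. The other pituitary hormone genes did not pass in limma. Growth hormone gh1 had a log2 change of 1.69 (SE 0.66, adjusted p = 0.108), tshb of 1.38 (SE 0.61, adjusted p = 0.153), pomc (LOC101064982) of 1.01 (SE 0.59, adjusted p = 0.273) and prolactin, prl, of 0.71 (SE 0.73, adjusted p = 0.562). For fshb it was 1.61 (SE 1.18, adjusted p = 0.395). Without the same fish the limma log2 change was 0.21 for prl (adjusted p = 0.762), 0.58 for pomc (adjusted p = 0.106), 0.97 for tshb (adjusted p = 0.0801) and 1.16 for fshb (adjusted p = 0.509). In that fit cga (1.82, adjusted p = 0.0162) and gh1 (1.24, adjusted p = 0.0410) passed. The calls of lhb and cebpd both ended with the FPKM sum as a covariate (log2 change 2.23 and 0.26), with either pituitary score as a covariate and with date means as samples. That of lhb also ended with a minimum mean of 5 FPKM, with quantile normalization, without the intensity trend, with the replicate block, with the week as a covariate and with 2 tide groups. Neither changed direction in these fits.

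**Figure D2:**
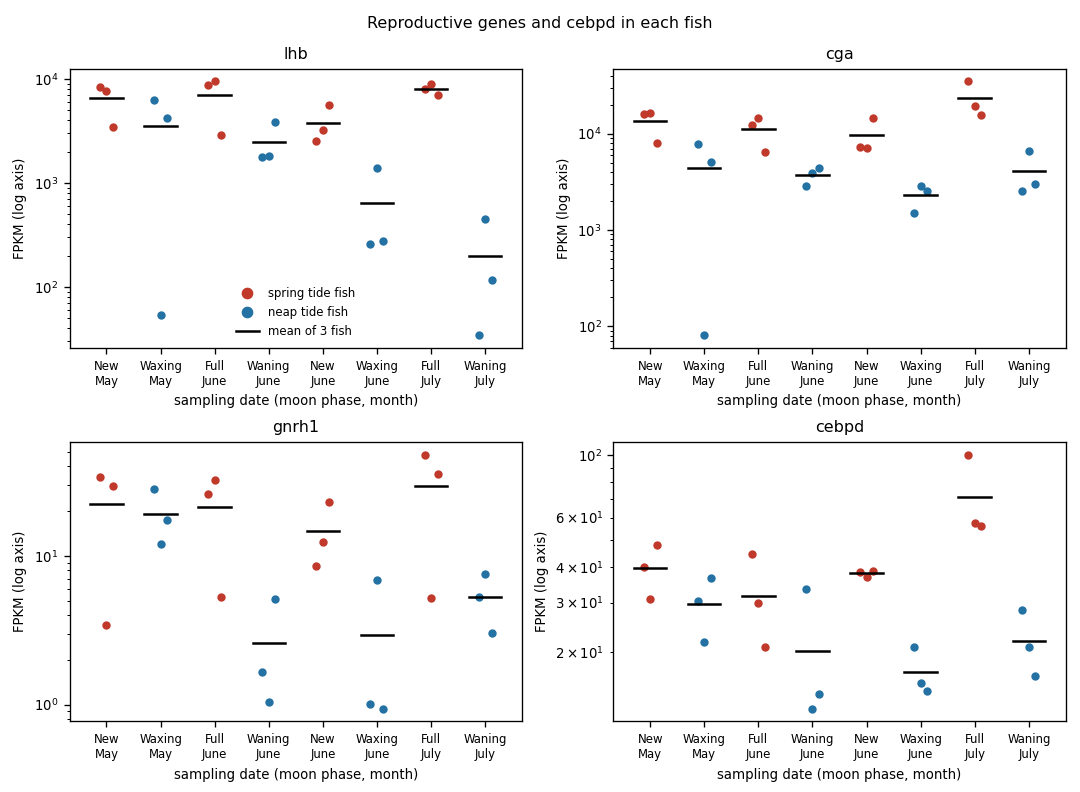
FPKM of lhb, cga, gnrh1 and cebpd in each fish on log axes, by sampling date; points are fish, red at spring and blue at neap tide, and bars are means of 3 fish. For lhb, cga and cebpd every spring date mean lay above every neap date mean, while gnrh1 at Waxing moon May (19.2) lay above the spring date New moon June (14.6). Without Waxing moon May fish 2 the mean of that date, 5259 for lhb and 33.5 for cebpd, lay above the lowest spring date mean, 3809 and 31.7.

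Over all genes, 225 rose and 736 fell at spring tide (limma with the date as a random block, adjusted p below 0.05; 961 of 17058, or 5.63%). The largest increase after lhb belonged to a gene named for an egg coat protein. LOC105416883 and LOC101080196, both zona pellucida sperm-binding protein 3-like, rose from 13.5 ± 5.80 to 152 ± 99.5 FPKM (log2 change 2.90, SE 0.80, adjusted p = 0.0388) and from 13.3 ± 6.72 to 124 ± 86.3 FPKM (2.63, SE 0.75, adjusted p = 0.0432). These 2 are near copies by name, and reads shared between such copies make their separate levels uncertain. A vitellogenin-like gene, LOC101062271, rose from 1.59 ± 1.61 to 14.5 ± 8.93 FPKM (2.42, SE 0.53, adjusted p = 0.0221). A zona pellucida 4-like gene, LOC101079966, had 3.20 against 0.0817 FPKM (1.53, SE 0.42, adjusted p = 0.0390). The prostacyclin synthase-like gene ptgis (LOC101079540) rose from 2.96 ± 1.85 to 13.9 ± 10.2 FPKM (2.07, SE 0.49, adjusted p = 0.0257), and the steroid-modifying enzyme hsd3b7 from 17.6 ± 7.29 to 41.9 ± 14.2 FPKM (1.31, SE 0.30, adjusted p = 0.0234). The others among the 12 largest increases were LOC115253119 (U2 spliceosomal RNA, log2 change 1.44), LOC101068406 (ripply2-like, 1.32), LOC101066901 (translocon-associated protein alpha-like, 1.25), LOC101061679 (cAMP-responsive element modulator, 1.2) and tuft1 (1.18).

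The claudin gene cldn5, which codes for a tight junction protein of brain endothelium, fell from 52.2 ± 6.18 FPKM at neap to 28.9 ± 3.84 at spring tide, with 24 of 24 fish on the side of their tide (log2 change -0.85, SE 0.11, limma, adjusted p = 0.000913). The thyroid hormone transporter gene slco1c1 (LOC101072817), also known from brain vessels, fell from 4.70 ± 1.61 to 1.89 ± 0.322 FPKM (-0.93, SE 0.14, adjusted p = 0.00206, 23 of 24 fish). The transcription factor osr1 fell from 32.0 ± 6.92 to 10.2 ± 2.96 FPKM (-1.58, SE 0.33, adjusted p = 0.0199, 21 of 24 fish) and the linker histone H1.0 gene LOC101076016 from 64.3 ± 24.8 to 27.9 ± 0.343 FPKM (-1.07, SE 0.20, adjusted p = 0.0134, 21 of 24 fish). The metalloreductase gene steap4 fell from 5.18 ± 2.76 to 1.34 ± 0.332 FPKM (-1.23, SE 0.31, adjusted p = 0.0297). The largest decrease was that of nfe2l1 (-1.76, SE 0.42, adjusted p = 0.0248, 8.26 against 2.26 FPKM). The others among the 12 largest decreases were LOC101077584 (AN1-type zinc finger protein 5-like, log2 change -1.51), LOC101072562 (visinin-like protein 1, -0.96), LOC101074263 (serum amyloid P-like, -0.88), LOC101079432 (LIM homeobox transcription factor 1-alpha-like, -0.86), LOC101063480 (SLIT and NTRK-like protein 3, -0.86) and b3galt4 (-0.82).

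The balance of increases and decreases depended on scaling. As deposited, 23.4% of the 961 calls were increases. With the libraries rescaled to a common sum (TPM), 116 genes rose and 2858 fell (3.90% increases). With median-ratio scaling 348 rose and 323 fell (51.9%), and with quantile normalization 269 rose and 436 fell (38.2%). TPM scaling moved the median log2 change of all tested genes to -0.166. With the log2 sum of FPKM of each library as a covariate 5 genes passed, all lower at spring tide, and with the pituitary score as a covariate 7 rose and 17 fell. With that score all 961 fold changes kept their sign, at a median ratio of 0.951 to those without it. The median SE rose from 0.0914 to 0.103. Leaving out a single date gave between 3 (without New moon May) and 5528 genes (without Waxing moon May).

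**Figure D3:**
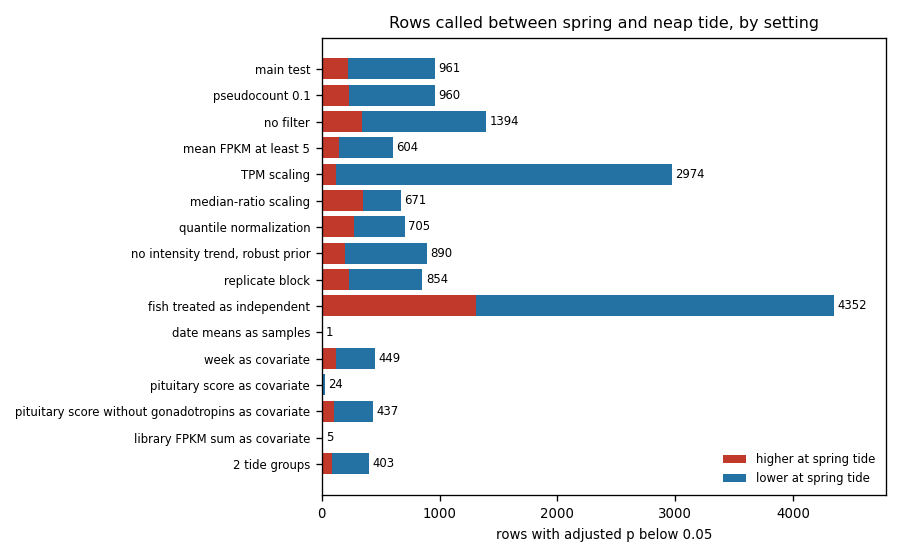
Number of genes with adjusted p below 0.05 between spring and neap tide (horizontal axis) under each setting (vertical axis), red for higher and blue for lower at spring tide. The count was 961 as reported, 2974 with TPM scaling, 4352 with the fish treated as independent, 5 with the library FPKM sum as a covariate and 1 with date means as samples.

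Of 21 gene lists fixed in advance, 10 lay higher at spring tide than the remaining genes when tested with limma's camera method and a preset correlation between genes; none of the 10 passed with an estimated correlation. The spring libraries also had the higher pituitary score and the higher mean FPKM sum given above. A list score, the median of the members' log2 levels minus each gene's mean, was compared over the 8 date means, outside the planned list tests. The unadjusted exact permutation p was 0.0286 for the pituitary list and 0.0571 for the reproductive axis and the unfolded protein response. It was 0.0857 for immediate early genes and the prostaglandin pathway, and 0.143 for ribosomal proteins. For neuropeptides, oxidative phosphorylation, cholesterol and interferon it was 0.229, 0.257, 0.286 and 0.543. In the reproductive axis list, 2 of 21 members rose over all genes tested. These were lhb and the estrogen receptor gene esr2 (LOC101075495; log2 change 0.73, SE 0.21, adjusted p = 0.0424). Adjusted over the list alone 6 rose and 1 fell. The list's median log2 change was 0.38 (adjusted p = 0.00164, and adjusted p = 0.111 with an estimated correlation). The median was 0.05 with the FPKM sum as a covariate, where the list did not pass (adjusted p = 0.137), and 0.10 with the pituitary score (adjusted p = 0.0229). The list holds gnrh1, so it is not fully independent of the study's own choice. In the pituitary list, which shares 10 of its 21 members with other lists, lhb rose over all genes and 2 members rose adjusted over the list alone (median 0.33, adjusted p = 0.00363, and adjusted p = 0.364 with an estimated correlation).

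Genes of the unfolded protein response, which act in folding and quality control in the endoplasmic reticulum, rose as a group (median 0.22, adjusted p = 1.70e-10, and adjusted p = 0.111 with an estimated correlation). Of 28 members 26 were higher at spring tide and 4 passed over all genes. Adjusted over the list alone 14 rose and 1 fell. The 4 were dnajc3 (log2 change 0.92, SE 0.22, adjusted p = 0.0245), creld2 (0.67, SE 0.17, adjusted p = 0.0320), the chaperone hspa5 (0.72, SE 0.22, adjusted p = 0.0486) and pdia3 (0.36, SE 0.11, adjusted p = 0.0486). Of 31 immediate early genes, which respond quickly to neuronal activity, fosl2 (0.39, SE 0.06, adjusted p = 0.00350, 36.4 ± 1.33 against 27.4 ± 2.12 FPKM, 23 of 24 fish), fosb (0.64), jund (LOC101076843, 0.45) and dusp5 (0.33) rose over all genes. Adjusted over the list alone 6 rose and 1 fell (median 0.18, adjusted p = 0.000146, and adjusted p = 0.115 with an estimated correlation). Both lists also passed under TPM, median-ratio and quantile scaling and with the FPKM sum as a covariate, with smaller medians under TPM scaling (0.10 for the unfolded protein response and 0.05 for immediate early genes) and with that covariate (0.13 for each).

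In the prostaglandin pathway 3 of 23 members rose, over all genes and adjusted over the list alone: ptgis and the prostaglandin E2 receptor genes ptger4 (LOC101070091; log2 change 0.72, SE 0.16, adjusted p = 0.0226) and ptger2 (0.68, SE 0.18, adjusted p = 0.0347). The list's median was 0.08 and turned to -0.01 under TPM scaling, although its test stayed positive relative to other genes under that scaling (as deposited, adjusted p = 0.00571, and adjusted p = 0.111 with an estimated correlation). The list did not pass with the FPKM sum as a covariate (adjusted p = 0.428). Among 35 hypothalamic neuropeptide genes agrp2 (0.74, SE 0.18, adjusted p = 0.0286) and nucb2 (1.12, SE 0.28, adjusted p = 0.0287) rose, in both ways of adjusting (median 0.17, adjusted p = 0.0145, and adjusted p = 0.200 with an estimated correlation). That list lost its call under median-ratio scaling (adjusted p = 0.0802), under quantile normalization (adjusted p = 0.0545) and with the FPKM sum as a covariate (adjusted p = 0.0509). The member nts (1.11, adjusted p = 0.0701) is described in the deposited table as nothepsin, not as neurotensin.

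The 82 tested genes of cytosolic ribosomal proteins were all higher at spring tide, with a median log2 change of 0.27, but only rpl15 (0.42, SE 0.12, adjusted p = 0.0388), rps12 (0.41, adjusted p = 0.0458) and rpl12 (0.36, adjusted p = 0.0485) passed over all genes and 0 adjusted over the list alone. Relative to other genes they rose as a group (adjusted p = 2.16e-25, and adjusted p = 0.200 with an estimated correlation). In their list score only 1 spring date lay above every neap date (exact permutation p = 0.143, n = 4 dates per tide). With the FPKM sum as a covariate they lay lower at spring tide (adjusted p = 3.14e-06). Of 102 oxidative phosphorylation genes, 76 were higher, with the cox7 gene LOC101064509 alone past the threshold over all genes (0.98, adjusted p = 0.0361) and 0 adjusted over the list alone. Their median was 0.12 and turned to -0.02 under TPM scaling (adjusted p = 1.53e-07, and adjusted p = 0.321 with an estimated correlation). The interferon response list (44 members, median 0.11, adjusted p = 0.0132, and adjusted p = 0.401 with an estimated correlation) and the cholesterol biosynthesis list (29 members, median 0.05, -0.07 under TPM scaling, adjusted p = 0.0348, and adjusted p = 0.401 with an estimated correlation) had 0 members past the threshold in either way of adjusting. Both lost their call under median-ratio scaling (adjusted p = 0.0579 for each). The oxidative phosphorylation, interferon and cholesterol lists did not pass and had the opposite direction with the FPKM sum as a covariate (adjusted p = 0.260, 0.223 and 0.987).

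The circadian clock list did not move one way (median 0.01, mean -0.01, adjusted p = 0.277), but 8 of its 40 members passed over all genes and adjusted over the list alone, 3 higher and 5 lower. The period gene per2 (LOC115246449) rose (log2 change 0.77, SE 0.15, adjusted p = 0.0134, 22 of 24 fish), while the repressor gene bhlhe41 (-0.60, SE 0.11, adjusted p = 0.0134) and the thyrotroph embryonic factor genes tef (LOC115246496, -0.59, SE 0.12, adjusted p = 0.0182) and tef (LOC101073097, -0.67, SE 0.16, adjusted p = 0.0234) fell. The fall of bhlhe41 lay at the full moons, because its level at the new moons was close to that of the neap dates (see new and full moons below). In the glucocorticoid and stress list the binding protein gene crhbp rose (1.00, SE 0.18, adjusted p = 0.00819) and klf15 (LOC101071465) fell (-0.49, SE 0.10, adjusted p = 0.0182), with 3 of 34 higher and 5 lower adjusted over the list alone; its median was -0.01, its mean 0.06 and its test positive (adjusted p = 0.596). In the thyroid list slco1c1, the receptor gene thra (LOC101071184, -0.40, adjusted p = 0.0378) and eya3 (-0.22, adjusted p = 0.0481) fell, and adjusted over the list alone 2 of 22 rose and 5 fell (adjusted p = 0.776 for the list). In the heat shock list hspa5 rose and hspd1 fell (-0.37, SE 0.08, adjusted p = 0.0233), with 2 of 29 higher and 3 lower adjusted over the list alone (adjusted p = 0.817 for the list).

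The remaining gene lists did not pass. For opsins, light and melatonin (10 members, adjusted p = 0.965) the melatonin receptor gene mtnr1a fell (log2 change -0.42, adjusted p = 0.0286) and 2 members fell adjusted over the list alone. For the C/EBP family (6 members, adjusted p = 0.104) cebpd rose, and adjusted over the list alone 1 rose and 1 fell; the family holds cebpd, which the study discusses. The hypoxia list (32 members, adjusted p = 0.0635) held pfkfb4 (LOC101075480, 0.38, adjusted p = 0.0347) as its 1 increase in both ways of adjusting. The steroid synthesis list (9 members, adjusted p = 0.446) held hsd3b7 as its 1 increase in both ways, with a median of -0.07 and a mean of 0.10. Inflammation (25 members, adjusted p = 0.0545), neurotransmitter enzymes (25 members, adjusted p = 0.828) and the cell cycle (24 members, adjusted p = 0.992) had 0 members past the threshold in either way; the last 2 had negative medians and means and a positive test.

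Of 16 cell type lists 1 rose and 3 fell with the preset correlation, and none passed with an estimated correlation. Over the 8 date means the unadjusted exact permutation p of the list score was 0.0286 for the hypothalamus and 0.0571 for neurons. It was 0.0857 for the tectum, thalamus and hindbrain and 0.286 for erythrocytes. Markers of neurons fell as a group relative to other genes at spring tide, with 27 of 31 lower (median -0.21, adjusted p = 0.00363, and adjusted p = 0.642 with an estimated correlation). Over all genes 2 members fell, 1 of them the synaptic vesicle gene sv2a (LOC101075303, log2 change -0.27, adjusted p = 0.0499). Adjusted over the list alone 6 fell. With the FPKM sum as a covariate the neuron list lay higher at spring tide (adjusted p = 0.0104), and with the pituitary score it did not pass (adjusted p = 0.109). Of 22 regional markers of the hypothalamus 19 were lower. Over all genes foxd1 (-0.59, SE 0.14, adjusted p = 0.0234), lef1 (-0.53), nkx2.4 (-0.55) and nkx2-1 (-0.35) fell, and 5 fell adjusted over the list alone (median -0.19, adjusted p = 0.0216, and adjusted p = 0.642 with an estimated correlation). Markers of the tectum, thalamus and hindbrain, which lie outside the sampled piece, were lower in 22 of 27. Over all genes mafb (-0.46), irx5 (-0.44) and gata3 (-0.35) fell, and 6 fell adjusted over the list alone (median -0.20, adjusted p = 0.0301, and adjusted p = 0.642 with an estimated correlation). Both regional lists lost their call under TPM scaling (adjusted p = 0.0852 and 0.0873) and with the FPKM sum as a covariate (adjusted p = 0.195 and 0.963), and the tectum list also with the pituitary score (adjusted p = 0.124). Erythrocyte markers rose as a group (12 of 15 higher, median 0.39, adjusted p = 0.00363, and adjusted p = 0.642 with an estimated correlation) with 0 members past the threshold in either way of adjusting. That list did not pass and had the opposite direction with the FPKM sum as a covariate (adjusted p = 0.417).

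Genes of endothelium and pericytes went both ways: over all genes 2 of 26 rose and 5 fell, and adjusted over the list alone 3 rose and 7 fell. Besides cldn5, the pericyte genes pdgfrb (log2 change -0.43, SE 0.09, adjusted p = 0.0175) and rgs5 (LOC101075850, -0.42, adjusted p = 0.0275) and the endothelial receptor gene tie1 (-0.40, adjusted p = 0.0225) fell. The list did not pass as a group (adjusted p = 0.418), but did so on the lower side with the FPKM sum as a covariate (adjusted p = 0.00239). For the telencephalon (21 members, adjusted p = 0.631) zic2 (-0.50) and nr2f1 (-0.37, adjusted p = 0.0225 for each) fell, over all genes and adjusted over the list alone. For oligodendrocytes (15 members, adjusted p = 0.996) olig2 fell (-0.53, adjusted p = 0.0424) and for the saccus vasculosus (10 members, adjusted p = 0.619) atp1b2 (LOC101071453, -0.47, adjusted p = 0.0302), each in both ways of adjusting. For microglia and macrophages (24 members, adjusted p = 0.266) ncf1 fell over all genes (-0.43, adjusted p = 0.0499) and 0 adjusted over the list alone. For skeletal muscle (17 members, adjusted p = 0.334) 0 passed over all genes, and 1 rose and 2 fell adjusted over the list alone. Radial glia (25 members, adjusted p = 0.225), lymphocytes (14, adjusted p = 0.225), photoreceptors (18, adjusted p = 0.225), ependyma (27, adjusted p = 0.225), connective tissue (34, adjusted p = 0.151) and epithelium (15, adjusted p = 0.126) had 0 members past the threshold in either way of adjusting.

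**Figure D4:**
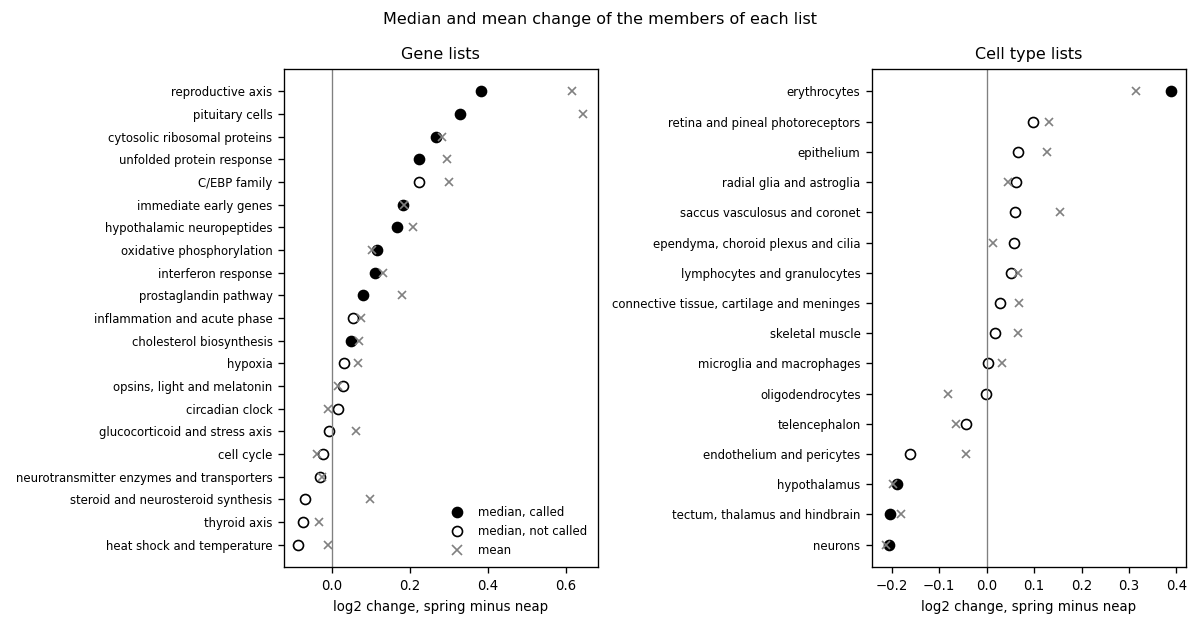
Median (circles) and mean (crosses) log2 change between spring and neap tide (horizontal axis) over the tested members of each list (vertical axis); filled circles mark lists with adjusted p below 0.05 at the preset correlation. Ribosomal proteins lay at 0.27 and neurons at -0.21 as deposited, and the medians of the prostaglandin, oxidative phosphorylation and cholesterol lists turned negative under TPM scaling.

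Limma's fry test, which asks whether a list's genes move at all and does not compare them with other genes, called 0 gene lists and 2 cell type lists (hypothalamus; tectum, thalamus and hindbrain) for movement in one direction, and 14 gene lists and 6 cell type lists for change in either direction. Of 460 annotation terms of 10 to 300 tested genes given in the deposited table, 21 rose and 5 fell with the preset correlation, and no test with an estimated correlation was run on terms. The structural constituents of the ribosome (92 genes, median log2 change 0.23, adjusted p = 7.21e-11) and hormone activity (35 genes, 0.21, adjusted p = 0.00803) were among those that rose. Protocadherins of the delta 2 class (27 genes, -0.27, adjusted p = 0.00504) and the alpha class (15 genes, -0.25, adjusted p = 0.0398) and voltage-gated potassium channels (31 genes, -0.25, adjusted p = 0.0291) were among those that fell.

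The design covers the tide change in both lunar cycles, which share no fish. Across the 17058 tested genes the log2 changes of the cycles had a Pearson r of 0.459 and a covariance of 0.0309, and 70.8% of genes had the same sign, against 31.8% to 67.3% for the other pairings of the dates. Genes are not independent replicates. Of the 9 ways to pair off the same dates this was the highest r, the next being 0.416. The sign of r, and which side of 50% the share of equal signs falls on, is arbitrary for other pairings, and the highest absolute r among them was 0.440. The sign of the covariance is arbitrary in the same way. It was -0.0333 in 1 other pairing, larger in size than the 0.0309 of the tide pairing. Being the highest of 9 is also the strongest outcome that this comparison can give. The test of a difference between the cycles (interaction) called 0 genes in limma, and 607 had an unadjusted p under 0.05, against 853 that chance alone gives. The smallest p-values, none of which passed (adjusted p = 0.993 for each), belonged to LOC101067285 (glypican-5-like, log2 difference 0.73), LOC101079150 (aminopeptidase N-like, 1.16), ecrg4 (1.01), the clock gene nr1d1 (LOC101076758, 1.09) and emp2 (1.35), larger in the later cycle, and to LOC101072929 (SOX-4, -0.71), dnajc6 (-0.52), LOC101071379 (MYCN, -0.42), rorb (LOC101076680, -0.94) and lmo4 (-0.64).

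**Figure D5:**
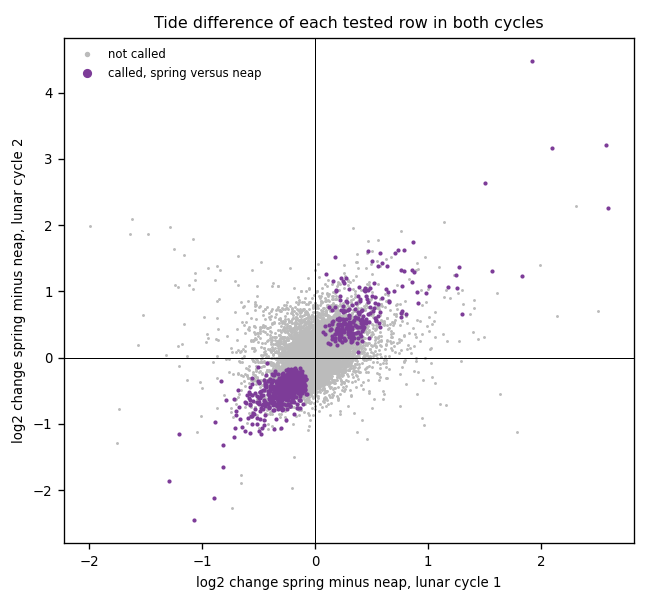
Spring minus neap log2 change of each tested gene in lunar cycle 1 (horizontal axis) and lunar cycle 2 (vertical axis); purple points are the 961 genes past the threshold, grey points the others. Over all 17058 genes r was 0.459 and 70.8% had the same sign in both cycles. The purple points were chosen by their change over both cycles, so their common sign is largely set by that choice.

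Within the spring tides, new and full moons were compared with 2 dates each. The clock repressor gene bhlhe41 was higher at new moon, with 10.1 ± 0.903 and 12.3 ± 3.00 FPKM at the new moon dates against 4.16 ± 0.369 and 4.46 ± 0.924 at the full moon dates (SD, n = 3 fish; log2 change 1.19, SE 0.16, limma, adjusted p = 0.00259). The potassium channel gene kcnma1 was higher at new moon (0.55, SE 0.10, adjusted p = 0.0439) and the inorganic pyrophosphatase-like gene LOC101072613 lower (-0.57, SE 0.09, adjusted p = 0.0292). These were the 3 genes that passed, while 2042 had an unadjusted p under 0.05 against 853 by chance. Genes vary together, so an excess or a shortfall against 853 does not by itself show a difference, here or in the other comparisons. The next by p did not pass: the clock genes nr1d2 (LOC101077948, 0.59, adjusted p = 0.0662) and per3 (0.65, adjusted p = 0.110), LOC101064665 (disks large homolog 2, 0.39, adjusted p = 0.0730), rpn2 (-0.33, adjusted p = 0.110), and LOC101075957 (ATF-4-like, -0.45), LOC101076158 (calponin-2, -0.42) and LOC101066257 (ER lumen retaining receptor 2-like, -0.45, adjusted p = 0.126 for each of these). The bhlhe41 call ended with date means as samples, which called 0 genes, and when either new moon date or Full moon June was left out. Of the 3 calls, 2 ended under TPM scaling and 2 with the pituitary score as a covariate.

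Within the neap tides, no gene passed between waxing and waning moons in limma (0 genes), and 486 had an unadjusted p under 0.05 against 853 by chance. The smallest p-values, all with an adjusted p of 0.997, belonged to hspe1 (log2 change 0.37), LOC105417119 (capicua, 0.31), brk1 (0.30), slc23a1 (0.36) and LOC101066144 (heme-binding protein 1-like, 0.30) on the side of the waxing moon. On the side of the waning moon they were fam181a (-0.50), slco1c1 (LOC101072817, -0.68), LOC101065064 (ASH1L-like, -0.31), LOC101063659 (synaptotagmin-like protein 1, -0.59) and bicral (-0.41). Without Waxing moon June 752 genes passed, but the waxing moon is then the single date Waxing moon May.

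Sampling ran from May to July, so the season moved with the date, and a slope per week was fitted with the tide in the model. Interferon response genes fell over the weeks as a group: 39 of 44 had a negative slope, with a median of -0.04 log2 per week (adjusted p = 4.11e-08, and adjusted p = 0.183 with an estimated correlation), and 5 fell adjusted over the list alone. Their smallest p-values belonged to ifih1 (-0.14 per week), cmpk2 (-0.25), dhx58 (-0.14) and usp18 (-0.17). Hypoxia genes rose as a group, with 24 of 32 positive and 3 higher adjusted over the list alone (median 0.02, adjusted p = 0.0363, and adjusted p = 0.699 with an estimated correlation); vegfa had a slope of 0.11, slc2a1 (LOC101063282) of 0.25 and epo of 0.16. Oxidative phosphorylation (median -0.01, adjusted p = 0.000355, and adjusted p = 0.715 with an estimated correlation), cholesterol biosynthesis (median -0.01, adjusted p = 0.0363, and adjusted p = 0.715 with an estimated correlation) and telencephalon markers (median -0.02, adjusted p = 0.0264, and adjusted p = 0.832 with an estimated correlation) fell as groups, each with 0 members past the threshold in either way of adjusting. The slope of the oxidative phosphorylation list did not pass under quantile normalization (adjusted p = 0.252), and that of the cholesterol list did not with the FPKM sum as a covariate (adjusted p = 0.0520). The other 17 gene lists and 15 cell type lists did not pass for the slope. Adjusted over the list alone, 2 thyroid genes rose, 1 glucocorticoid gene fell and 2 oligodendrocyte genes fell. For immediate early genes, the C/EBP family, the prostaglandin pathway, photoreceptors, skeletal muscle, epithelium and markers of the tectum, thalamus and hindbrain the median and mean slopes were positive and the test negative. The median and the mean differed in sign for the circadian clock, neuropeptides, endothelium and steroid synthesis.

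No single gene passed for the slope in limma (0 genes), and 1446 had an unadjusted p under 0.05 against 853 by chance. The smallest adjusted p, 0.0516, was shared by the mitochondrial protein gene stmp1 (-0.15 per week), LOC105417603 (MYCBP-associated protein, -0.25), hsdl2 (-0.07), g0s2 (-0.27), LOC101075447 (-0.09), catalase cat (-0.06) and rbm33 (0.08). Next among negative slopes came LOC115249345 (U1 spliceosomal RNA, -0.29, adjusted p = 0.0589), celf2 (-0.07), slc25a34 (-0.11) and ifih1. Among positive slopes they were cdc40 (0.05), LOC101066263 (potassium channel K5-like, 0.10), LOC105416297 (0.09), LOC101074476 (0.04), pank4 (0.04), pde7b (0.06), srebf1 and acaca (0.07 each) and vegfa. The date means of fshb were 3499, 1421, 1291, 321, 537, 128, 75.2 and 93.9 FPKM in order, a slope of -0.70 log2 per week (SE 0.22) that did not pass (limma, adjusted p = 0.397). With the FPKM sum of the library as a covariate 40 genes passed for the slope, 8 rising and 32 falling.

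A limma F test of the 8 dates against the spread of 3 fish per date, without a date block, called 7040 of 17058 genes (41.3%). In the same form, with fish treated as independent, the tide contrast called 4352. The heat shock protein 90 gene hsp90aa1 (LOC101068853) was highest at Waxing moon June (522 FPKM) and Waning moon June (365 FPKM) and lowest at New moon May (131 FPKM, F = 40.7, adjusted p = 1.72e-06). Its co-chaperone gene fkbp4 was highest at the same 2 dates and lowest at the same date (F = 33.4, adjusted p = 4.08e-06). The smallest p-values belonged to LOC101066940 (a transmembrane protein gene, F = 46.2, adjusted p = 1.59e-06) and LOC101079760 (SRSF5-like, F = 42.9, adjusted p = 1.59e-06). The others among the 10 smallest were egfl6, stmp1, pknox1, LOC101068338 (sodium/potassium-transporting ATPase beta-233-like), LOC105419770 (spindlin-1-like) and LOC101077362 (clathrin heavy chain 1-like).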

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

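The rule for single values compared each library with the other 5 of its moon phase and was set in advance. It marked 16 of 188 groups, where about 9 would be marked by chance. For Waxing moon May fish 2, on the log2(FPKM + 1) scale, cga was 6.35 (others 10.6 to 12.9), gh1 4.25 (8.76 to 10), prl 2.71 (8.03 to 9.20), pomc 8.24 (13.1 to 13.8) and tshb 1.06 (5.19 to 6.53). In the same fish the pituitary list score was -2.26 (others -0.137 to 0.172) and the neurotransmitter list score 0.142 (-0.0392 to 0.0236). For Waning moon July fish 1 the FPKM sum was 484265 (others 443289 to 454562), the ribosomal list score 0.213 (-0.308 to -0.210) and the cholesterol list score 0.104 (-0.128 to -0.0443). For Full moon June fish 3 lhb was 11.5 (others 12.8 to 13.2) and the neuron list score 0.155 (-0.324 to -0.193). The others were tshb in Full moon July fish 2 at 8.05 (6.34 to 6.86), the thyroid list score in Waning moon June fish 2 at -0.00186 (0.0828 to 0.112), the inflammation list score in New moon June fish 3 at 0.0769 (-0.109 to -0.0421) and the oligodendrocyte list score in Waxing moon May fish 3 at -0.550 (-0.0480 to 0.140).

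For the number of tide genes, the covariates for the FPKM sum and for the pituitary share without gonadotropins were chosen after seeing the result. With the FPKM sum as a covariate the median ratio of fold changes with and without it was 0.429, so most of the change moved with that sum. The sum comes from the same values as the genes and had r = 0.989 with the first principal component over 8 date means (exact permutation p = 2.48e-05), so this test cannot separate a technical change from a biological one. With the pituitary score without gonadotropins the ratio was 0.996, where 0.75 or more was set to speak against the tissue share. The calls fell to 437 as the median SE rose from 0.0914 to 0.0977. With the planned full score the ratio was 0.951, and 24 genes passed as the median SE rose to 0.103. Waxing moon May fish 2 had a score without gonadotropins of 4.06, and the next lowest library 8.53. That 1 library can set the fit, so the ratio does not exclude the tissue share as a source. Of 100 random splits of the dates, 12 gave as many genes as the tide split (951 when the correlation comes from every 8th gene; highest other 5161), so chance is not excluded for the number. The split with 5161 genes set Waxing moon May with 3 spring dates and New moon June with 3 neap dates. The dates on the side of Waxing moon May had mean FPKM sums of 499 to 541 kFPKM. Those on the side of New moon June had 442 to 482 kFPKM. This split was therefore also a split of the dates by their FPKM sum, a structure beyond the tide.

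For lhb and cga the test was chosen after seeing the result. Relative to 5 other hormone genes of the pituitary, 58.7% of their difference was left, a log2 change of 1.61 of 2.75 (exact permutation p = 0.0571, n = 4 dates per tide). The share of pituitary in the piece therefore remains open as part of the difference.

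For the unfolded protein response list the covariates for the FPKM sum and for the pituitary score without gonadotropins were chosen after seeing the result, while the full pituitary score was planned. With the pituitary score without gonadotropins as a covariate 83.1% of the median change was left, and with the full pituitary score 71.9%. The member genes spread widely (SD 0.203 log2 around a median of 0.187 with the first of these), but that spread does not measure the uncertainty of the median. No interval for the part left was computed, so the share of pituitary stays open. With the FPKM sum 57.9% was left, which leaves that explanation open too.

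The random splits were planned in advance. The 7040 genes among dates were matched in 1 of 100 shuffles, the observed one (highest other 1033), which is the smallest share that 100 can give. Chance is therefore an unlikely source of that count. The shuffles cannot tell a biological difference between dates from one of preparation, because the labels give no batches. For the 10 gene lists between tides 18 of 100 splits gave as many (highest other 12), for the 4 cell type lists 63 of 100 (highest other 12), for the 26 annotation terms 37 of 100 (highest other 69) and for the 8 clock genes 10 of 100 (highest other 15). For the trend, 94 of 100 gave as many as its 4 gene lists (highest other 12) and 92 of 100 its 1 cell type list (highest other 11). Chance is not excluded for any of these list, term and clock gene counts. For the 0 genes of the trend every split, 100 of 100, gives at least as many (highest other 855), so that test says nothing. Too few splits exist for the 3 genes of new against full moon (1 of 3; highest other 0), the 0 of waxing against waning moon (3 of 3; highest other 23) and the 0 of the interaction (18 of 18; highest other 16).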

How the results depend on the processing

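Each result was repeated with other settings, and those that moved are given here. The cause was not tested for any change with a fish or date left out.

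The count of genes between spring and neap tide was 961. It became 604 with a mean FPKM of at least 5, 2974 with TPM scaling, 4352 with the fish treated as independent, 1 with date means as samples, 449 with the week as a covariate, 24 with the pituitary score as a covariate, 437 with the pituitary score without gonadotropins as a covariate, 5 with the library FPKM sum as a covariate and 403 with 2 tide groups. It was 960 with a pseudocount of 0.1, 1394 without a filter, 671 with median-ratio scaling, 705 with quantile normalization and 890 without the intensity trend and with a robust prior. Of the named genes that passed, 1 changed sign: sv2a (LOC101075303), with a log2 change of 0.0025 with the FPKM sum as a covariate. Most named genes kept their sign but not their call. Of 70 calls listed for named genes, 69 ended with date means as samples, 68 with the FPKM sum and 63 with the pituitary score as a covariate. With 2 tide groups 37 ended.

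Of the 5 targeted genes, 3 had an exact permutation p under 0.05. Without Waxing moon May fish 2, a test chosen after the data had been seen, 1 did.

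Between new and full moon the count was 3. It became 6 without a filter, 5 with the replicate block, 880 with independent fish, 0 with date means, 7 with the week as a covariate and 1 with the pituitary score as a covariate. For the trend the count was 0. It became 11 without a filter, 1 with TPM scaling, 7 with median-ratio scaling, 6 with quantile normalization, 299 with independent fish, 10 with the pituitary score and 40 with the FPKM sum as a covariate. The 7040 genes that differed among dates became 1313 with the FPKM sum as a covariate.

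For lists between tides the counts were 10 gene lists and 4 cell type lists. Cell type lists became 2 with a mean FPKM of at least 5 and 2 with the pituitary score, and gene lists became 4 with the FPKM sum as a covariate. With an estimated correlation both became 0, and with fry in one direction 0 gene lists and 2 cell type lists passed. For the trend the counts were 4 gene lists and 1 cell type list. Without a filter they became 2 and 2. Cell type lists became 3 with a mean FPKM of at least 5, 5 with TPM scaling and 2 with the FPKM sum as a covariate. With an estimated correlation and with fry in one direction both kinds became 0, and with fry in either direction the cell type lists became 0.

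With the FPKM sum as a covariate these lists had the opposite direction between tides: interferon response (adjusted p = 0.223), cholesterol biosynthesis (0.987), oxidative phosphorylation (0.260), cytosolic ribosomal proteins (3.14e-06), neurons (0.0104), microglia and macrophages (0.050), erythrocytes (0.417), lymphocytes and granulocytes (0.0221) and connective tissue, cartilage and meninges (0.0475). Beyond those named, these lists that did not pass as reported passed under the scalings, the FPKM sum or the pituitary score. They were endothelium with the FPKM sum (lower, 0.00239) and hypoxia with the pituitary score (higher, 0.0429). Under TPM scaling they were inflammation (0.00635), lymphocytes (0.0471), photoreceptors (0.0225), connective tissue (0.0225) and epithelium (0.0471). Each of these TPM results was higher only relative to other genes, and the list's median log2 change was negative.

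With single fish left out the tide count lay between 288 and 1966. It moved by more than a factor of 1.5 without New moon May fish 1 (311) or 3 (571), Waxing moon May fish 1 (1966), Full moon June fish 1 (514), 2 (544) or 3 (1670), Waning moon June fish 2 (608) or 3 (581), New moon June fish 3 (571), Waxing moon June fish 1 (572) or 2 (628), Full moon July fish 2 (541) or 3 (557), and Waning moon July fish 2 (288) or 3 (544). With single dates left out it was 3 without New moon May, 5528 without Waxing moon May, 1184 without Full moon June, 64 without Waning moon June, 113 without New moon June, 56 without Waxing moon June, 13 without Full moon July and 19 without Waning moon July. No gene that passed changed sign in these fits.

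Other counts with fish left out, then with dates left out, lay in these ranges: any date 5929 to 7643 and 4804 to 7077; new and full moon 1 to 117 and 0 to 128; waxing and waning moon 0 to 0 and 0 to 752; trend 0 to 4 and 0 to 39; interaction 0 to 0 and 0 to 1. For the tide, gene lists lay at 9 to 13 and 8 to 14 and cell type lists at 3 to 4 and 1 to 8. For the trend, gene lists lay at 2 to 8 and 3 to 7 and cell type lists at 0 to 6 and 2 to 7. The slope of the oxidative phosphorylation list changed direction in 1 of 32 fits, without Waxing moon May (adjusted p = 0.0450), and its lowest adjusted p was 4.21e-07 without New moon May. That of the ribosomal list changed direction in the same 1 fit (2.89e-20), and its highest adjusted p was 0.986 without New moon June.

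Fish numbers might mark a shared batch across dates. Over 84 pairs of residual profiles with the same number the correlations ran from -0.303 to 0.243 with a median of 0.0165, 23 lay above 0.1, and 13 of 24 fish had their best match at their own number. No chance value was computed for these counts, so a shared batch by fish number is neither shown nor excluded. With the fish number as an added block 854 genes passed between tides, 786 of them shared with the 961.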

Other observations

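Some of the genes with the largest tide changes varied widely between fish. The zona pellucida 3-like gene LOC105416883 ran from 0.33 to 598 FPKM over the fish, with date means of 37.6, 12.1, 149, 17.3, 142, 6.01, 280 and 18.8, and an SD of 275 at Full moon July (n = 3 fish). The vitellogenin-like gene LOC101062271 had date means of 16.5, 3.73, 24.2, 1.89, 2.63, 0.59, 14.4 and 0.143 FPKM. Which cells carry them is not given by these data.

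Among the clock genes, nr1d1 (LOC101076758) had date means of 51.9, 59.3, 32.9, 40.4, 63.1, 37.9, 49.0 and 24.6 FPKM, and bhlhe41 was lowest at both full moons. Prolactin, prl, was highest at the last 2 dates, with date means of 535, 299, 296, 364, 500, 357, 1444 and 1167 FPKM, without passing for the slope (log2 0.38 per week; limma, adjusted p = 0.501). The heat shock gene hsp90aa1 (LOC101068853) peaked at Waxing moon June with 522 ± 54.3 FPKM (SD, n = 3 fish).

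Over the 8 date means the FPKM sum of a library went with the ribosomal list score (r = 0.966, exact permutation p = 0.000124, rho = 0.976 with p = 0.000397; r = 0.909 without the 2 dates farthest from the median), with oxidative phosphorylation (r = 0.868, exact permutation p = 0.00605, rho = 0.905 with p = 0.00456; 0.867 without the 2) and with the unfolded protein response (r = 0.839, exact permutation p = 0.00784, rho = 0.905 with p = 0.00456; 0.782 without the 2). It ran against the neuron list score (r = -0.970, exact permutation p = 9.92e-05, rho = -0.952 with p = 0.00114; -0.956 without the 2). Adjusted over these 4 the p-values are 0.000248, 0.00784, 0.00784 and 0.000248. The sum contains the levels of the same genes, and these 4 are among the lists called between tides. The adjustment does not cover the other lists, so these p-values are not independent support for a relation.

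Waxing moon May stood apart from the other neap dates in its FPKM sum (501 kFPKM) and in gnrh1 (19.2 FPKM), and leaving it out raised the tide count from 961 to 5528 genes. Of the 12 splits with as many genes as the tide split, 3 had the dates of the tide split and 9 exchanged Waxing moon May for a spring date.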
